A study of Astyanax mexicanus with 18 samples.

How the data were processed

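The values analysed were TPM per gene and library, deposited by the authors, and 18187 of the listed genes carry a symbol. Per the submitters' processing notes, bcl2fastq 2.18, STAR 2.6.1c, RSEM and Bowtie2 were used. The roles of STAR and Bowtie2, the genome build, the annotation release and the strand setting are not given in the sources used here. Per the labels' protocols, polyA RNA was made into stranded libraries and sequenced as single reads. The ChIP-seq libraries were not analysed here. All 12 RNA-seq libraries were kept, and no 2 of the 66 pairs of libraries were identical.

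TPM are not counts, so the values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3. The fit held 4 group means, an eBayes prior with a mean-variance trend, 8 residual degrees of freedom and 3.303 prior degrees of freedom. The 13157 genes with at least 1 TPM in at least 3 of 12 libraries were tested, and 3768 genes were at 0 in all libraries. A gene was called at an adjusted p under 0.05 by Benjamini and Hochberg, over all tested genes of a comparison. The 5 comparisons were refed against starved fish in each population, Pachón cavefish against surface fish in each feeding state, and the difference between the refeeding responses. No further scaling was applied to TPM, which depend on the most abundant genes. The median log2 fold change over all tested genes was -0.04 for surface refeeding, 0.17 for Pachón refeeding, -0.13 and 0.18 between starved and refed populations, and 0.29 for the difference in response.

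Of 41 gene lists fixed by symbol before the data were examined, 27 of pathways and 14 of cell types, 36 had at least 5 tested members. These were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, each adjusted over the 36 lists. With the estimated correlation no list was called in any comparison. With the preset correlation, splits of the libraries that mix the groups often gave as many list calls. These calls are therefore weak evidence alone. The counts of members also use p adjusted over the members of a list alone. Genes were named by a rule set before the data were examined. It takes the 8 genes with a symbol that rose and the 8 that fell most among called genes with non-overlapping libraries and a mean of at least 5 TPM in a group. It adds up to 4 members of each described list with the smallest p, and a fixed set of metabolic and clock genes. The text names only part of what the rule gives, and this part was chosen after it was seen which calls stood under the alternatives, mostly in favour of those that did. Of 370 called genes that the rule gives over all lists and comparisons, 214 stood under all alternatives run for single genes, against 128 of the 138 named and 86 of the 232 left out. Of the 8 highest and 8 lowest genes, the report leaves out HBE1 (1 of many), hspa5 and dnajb9b for surface refeeding. It also leaves out mt2 (1 of many), siae and glud1a between starved and afp4, hspb8, siae and rgs11 between refed populations. Of these 10 calls, 8 ended under at least 1 alternative.

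In a test on simulated changes, 200 of 13157 genes were changed in the Pachón refeeding comparison. They were drawn from genes with a mean log2(TPM + 1) of at least 2, and noise was drawn independently for each gene. Beside them the 20 tested members of the glycogen metabolism list were raised 2-fold, and these are not in the counts below. The fit called 0 of 67 genes changed 1.5-fold, 6 of 67 changed 2-fold and 40 of 66 changed 4-fold, all in the right direction, and 0 unchanged genes. In this simulation, changes of 4-fold or less were therefore often missed. Far fewer genes changed in it than the 4024 called in the real comparison, where the adjustment is less strict. The shares found here therefore need not hold for the real data.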

Results

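Liver RNA was sequenced from the surface form of Astyanax mexicanus, an eyed river fish, and from the Pachón population, blind cavefish of the same species, at an age of 4 months. Fish were fasted for 4 days, and those called refed here then received a single meal of 10 mg of feed and were dissected 3 hours later. The 2 populations and 2 feeding states make 4 groups with 3 libraries each, and per the labels 3 surface fish and 3 Pachón cavefish were refed. Another 6 libraries of the series, ChIP-seq of Ppar gamma and its inputs, were not analysed here. Levels were given as TPM per gene and library, which keep no sequencing depth, so the depth is unknown. Between 10952 and 12123 genes per library had at least 1 TPM, and the 10 most abundant genes took 24.9% to 32.8% of the TPM. The gene with the highest TPM was fabp10a, a fatty acid binding protein of the liver, in 11 of the 12 libraries. Pearson r across genes, which are not independent replicates, was 0.9 to 0.938 between libraries of starved surface fish, 0.924 to 0.955 in refed surface fish, 0.96 to 0.972 in starved Pachón cavefish and 0.958 to 0.973 in refed Pachón cavefish, against 0.787 to 0.919 between groups. Changes below are log2 fold changes on the log2(TPM + 1) scale with the SE of the fit, which understate the change of low genes, and levels are mean TPM ± SD of 3 libraries. Unless stated otherwise, the libraries of the groups compared did not overlap for a named gene that changed. Chance gives this in 10% of genes for 3 libraries against 3. The naming rule required it of the 8 highest and 8 lowest genes, so for them it is no further evidence.

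**Figure D1:**
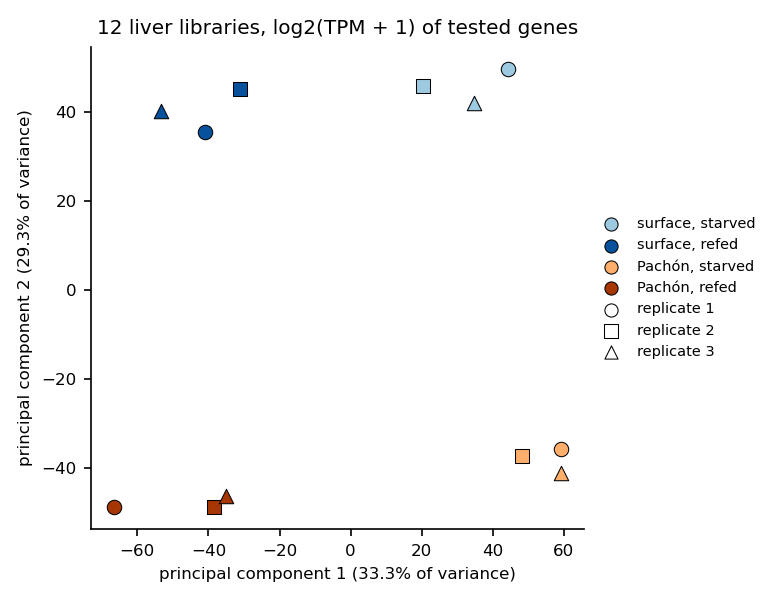
Position of the 12 liver libraries on the first principal components of log2(TPM + 1) over the tested genes, with colour for the group and shape for the replicate number. Component 1 (33.3% of the variance) separates starved from refed libraries and component 2 (29.3%) separates surface fish from Pachón cavefish.

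PPARG (ENSAMXG00000043041), the nuclear receptor that drives fat storage and that the series names, had more transcript in Pachón cavefish than in surface fish in both feeding states. Starved surface fish had 13.7 ± 4.94 TPM and starved Pachón cavefish 49.3 ± 22.4 TPM (SD, n = 3), a log2 fold change of 1.74 ± 0.35 (limma adjusted p = 0.00823). After refeeding the levels were 17.6 ± 4.12 TPM in surface fish and 64.5 ± 11.1 TPM in Pachón cavefish, a log2 fold change of 1.82 ± 0.35 (limma adjusted p = 0.00579). The meal itself gave no call for PPARG, with a log2 fold change of 0.38 ± 0.35 in surface fish (limma adjusted p = 0.494) and 0.46 ± 0.35 in Pachón cavefish (limma adjusted p = 0.352). The difference between these responses was 0.09 ± 0.49 (limma adjusted p = 0.949), and its sign turned under other scalings. Of 21 measured members of a fixed list of PPARG and its adipogenic targets, 2 were higher and 2 lower in starved Pachón cavefish than in starved surface fish (2 and 2 adjusted over the list alone, camera adjusted p = 0.818, adjusted p = 0.903 with an estimated correlation). Among refed fish 4 members were higher and 1 lower (4 and 1 adjusted over the list alone), where the median of the list (-0.05) and its test pointed down and its mean (0.37) up (camera adjusted p = 0.664, adjusted p = 0.916 with an estimated correlation). The members called in both states were PPARG, acsl1a and cidec, of which acsl1a, which activates fatty acids for storage or oxidation, was higher in Pachón cavefish by 2.05 ± 0.27 when starved and 1.36 ± 0.27 when refed. The lipid droplet gene cidec was lower by 1.44 ± 0.24 and 1.25 ± 0.24 in the same comparisons. The summed TPM of 9 adipocyte marker genes, cidec among them, averaged 957 and 581 in starved and refed surface fish and 284 and 258 in starved and refed Pachón cavefish. The highest sum, 1661, was in Surface_starved replicate 2, the library with the lowest summed TPM of the hepatocyte markers, 85221 against 152144 to 239214 in the others.

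**Figure D2:**
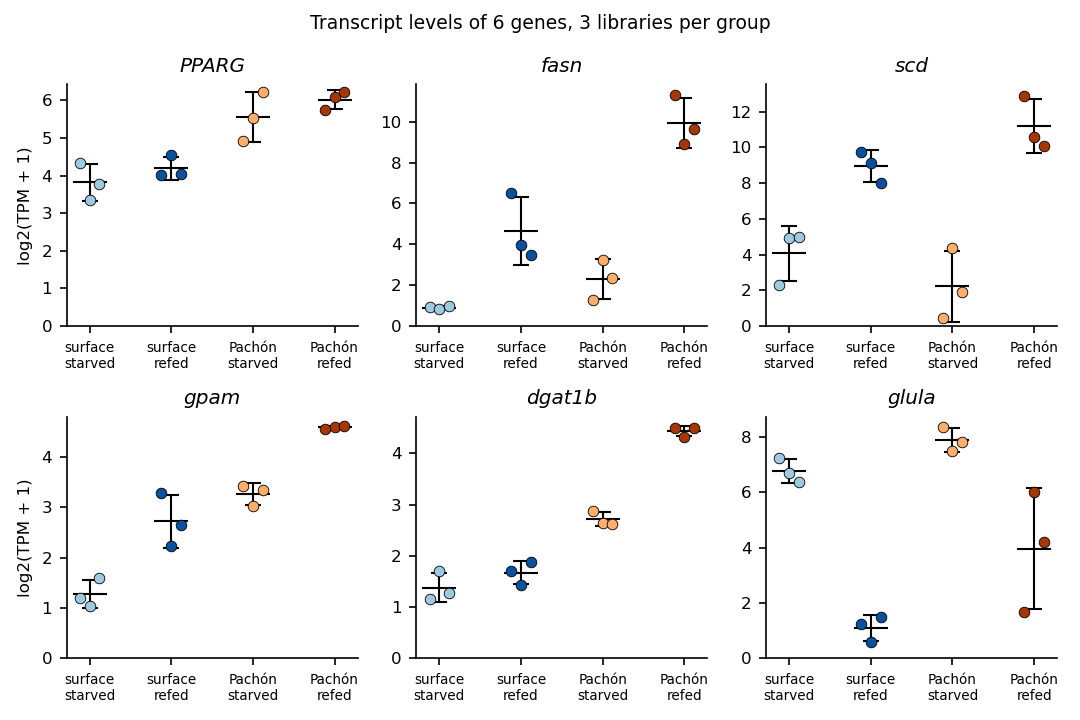
Transcript levels of PPARG, fasn, scd, gpam, dgat1b and glula as log2(TPM + 1), one point per library, with the mean and SD of 3 libraries per group as black bars. PPARG separates the populations in both feeding states, while fasn, scd and glula separate starved from refed libraries in both populations.

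The first comparison asked which liver genes had changed in surface fish 3 hours after a meal that ended a 4-day fast. The gene scd (ENSAMXG00000004360), the desaturase that makes monounsaturated fatty acids, rose by 4.88 ± 1.06. Its level went from 21.3 ± 15.1 to 553 ± 301 TPM (SD, n = 3, limma adjusted p = 0.0105). fasn (ENSAMXG00000012577), the fatty acid synthase, rose by 3.75 ± 0.80, from 0.873 ± 0.0802 to 38.7 ± 45.8 TPM (limma adjusted p = 0.00953). The chaperone gene HSP90a rose by 4.31 ± 0.46, the liver transcription factor gene cebpa by 4.08 ± 0.72 and ATAD3A, which encodes a mitochondrial membrane protein, by 3.10 ± 0.45 (limma adjusted p of 0.0039 or lower). Among genes that fell, the glutamine synthetase gene glula (ENSAMXG00000019301) fell by 5.67 ± 0.81, from 112 ± 35.9 to 1.21 ± 0.652 TPM (limma adjusted p = 0.00146). Expression of ddit4, an inhibitor of mTOR signalling, fell by 4.93 ± 0.71. The amino acid transporter gene slc43a2a fell by 4.52 ± 0.73, ypel3 fell by 3.8 ± 0.39, and pdk4, a brake on glucose oxidation, fell by 3.57 ± 0.54. The stress gene tp53inp1 fell by 3.49 ± 0.72, the Wnt receptor gene fzd9b fell by 3.48 ± 0.42 and the organic cation transporter gene slc22a16 fell by 3.48 ± 0.45. These 7 genes from ddit4 on had limma adjusted p of 0.00835 or lower. Of the metabolic genes fixed in advance, gpam, the first step of glycerolipid synthesis, rose by 1.44 ± 0.26, irs2b, an adaptor of the insulin receptor, fell by 3.18 ± 0.66, and g6pca.2, glucose-6-phosphatase, fell by 1.55 ± 0.36 (limma adjusted p of 0.0136 or lower). All 3 calls ended when only the 6 surface libraries were fitted, as did the next. Glucokinase gene gck rose by 4.20 ± 1.20 with overlapping libraries, a call that also ended with no filter, with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without Surface_starved replicate 1 or 3 or Surface_refed replicate 1 or 2 (limma adjusted p from 0.0324 up to 0.102 with 1 library left out).

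Of 36 gene lists fixed in advance, camera with the preset correlation called 6 for surface refeeding, and with an estimated correlation none (lowest adjusted p = 0.219). The preset correlation gave at least 6 lists in each of 10 splits of these libraries, the real one included, with up to 17 in another. The number of list calls therefore does not set the real grouping apart. In ribosome biogenesis 26 of 43 members rose, 1 fell and 16 passed no test (30 and 2 adjusted over the list alone). The ribosome biogenesis list had a median of 1.18 (camera adjusted p = 8.59e-12, adjusted p = 0.97 with an estimated correlation). Its members wdr75, rrp9 and utp20, which process ribosomal RNA, rose by 1.95 ± 0.28, 1.97 ± 0.30 and 1.20 ± 0.18. Among autophagy and lysosome genes 2 of 41 members rose, 16 fell and 23 passed no test (2 and 20 adjusted over the list alone). The autophagy and lysosome list had a median of -0.69 (camera adjusted p = 1.04e-06, adjusted p = 0.219 with an estimated correlation). The kinase gene ulk1b, which starts autophagy, fell by 1.73 ± 0.17, and ATG14 and ATG2A, which act in forming the autophagosome, fell by 1.99 ± 0.22 and 1.88 ± 0.21. In fatty acid oxidation and ketogenesis 0 of 39 members rose, 11 fell and 28 passed no test (1 and 16 adjusted over the list alone). The fatty acid oxidation list had a median of -0.82 (camera adjusted p = 1.88e-06, adjusted p = 0.97 with an estimated correlation). The peroxisomal acyltransferase gene crot fell by 2.6 ± 0.27, the mitochondrial dehydrogenase gene acadvl fell by 1.79 ± 0.24 and the monoglyceride lipase gene mgll fell by 1.73 ± 0.19. Of the proteasome list 6 of 36 members rose, 0 fell and 30 passed no test (4 and 0 adjusted over the list alone). The proteasome list had a median of 0.65 (camera adjusted p = 2.4e-06, adjusted p = 0.97 with an estimated correlation). Its member psmd11b rose by 1.40 ± 0.35, a call that ended without Surface_refed replicate 3 (adjusted p = 0.0685) and when only the 6 surface libraries were fitted (adjusted p = 0.0966). Among unfolded protein response genes 5 of 32 members rose, 0 fell and 27 passed no test (2 and 0 adjusted over the list alone). The list was called up (camera adjusted p = 0.000277, adjusted p = 0.97 with an estimated correlation), and its co-chaperone gene dnajb9a rose by 2.29 ± 0.39. No cytosolic ribosomal protein gene of 75 was called, and the list was called down against other genes with a median of -0.19 (camera adjusted p = 0.0237, adjusted p = 0.97 with an estimated correlation). This call ended under quantile normalization, with library weights, with TPM rescaled without the 20 most abundant genes, with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without any of Surface_starved replicate 1 or 2 and Surface_refed replicate 1 or 3 (adjusted p up to 0.401 with 1 library left out). In fatty acid synthesis 2 of 27 members rose, 1 fell and 24 passed no test (2 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.579, adjusted p = 0.97 with an estimated correlation). The members that rose were scd and fasn, and acacb, a carboxylase whose product blocks fatty acid oxidation, fell by 2.70 ± 0.23. By fry, the lists of ribosome biogenesis (adjusted p = 0.0438), autophagy (adjusted p = 0.000197), fatty acid oxidation (adjusted p = 0.0438) and glycolysis (adjusted p = 0.0464) were called. Glycolysis genes rose in 5 and fell in 1 of 29 members (5 and 1 adjusted over the list alone) without a camera call (camera adjusted p = 0.194, adjusted p = 0.97 with an estimated correlation). Not called by fry were the proteasome (adjusted p = 0.302), the unfolded protein response (adjusted p = 0.364) and ribosomal proteins (adjusted p = 0.453). In all, 1188 genes were higher and 1273 lower among 13157 tested by limma, 2461 together, and 730 and 720 of these changed at least 2-fold. The fit pooled the spread over all groups. Surface libraries correlated less with each other than Pachón libraries did, so the pooled spread may be too small for surface fish. With only the 6 surface libraries fitted, 837 genes were called, and part of this drop can come from fewer libraries. Without Surface_refed replicate 3 the number called was 1406, and with TPM rescaled without the 20 most abundant genes 60.1% of the calls were higher (1667 against 1108) in place of 48.3%. Surface_refed replicate 3 had a summed TPM of macrophage and Kupffer cell markers of 759, against 118 and 138 in the other refed surface libraries. Surface_starved replicate 3 had 134 TPM of intestine markers, against 11.4 and 16.8 in the other starved surface libraries. Summed TPM of vitellogenin and egg-protein genes were 4237 to 7188 in starved and 3537 to 4087 in refed surface libraries, and of ovary markers 4.81 to 8.71 and 3.18 to 4.79.

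The second comparison asked the same of Pachón cavefish, where the lipogenic genes scd, fasn, aclya and thrsp were among the 8 highest rises of the genes chosen by the fixed rule. Expression of scd rose by 8.96 ± 1.06, from 7.62 ± 10.6 to 3412 ± 3621 TPM (SD, n = 3, limma adjusted p = 0.000231). fasn rose by 7.66 ± 0.80, from 4.63 ± 3.48 to 1267 ± 1095 TPM (limma adjusted p = 0.000145). The citrate lyase gene aclya (ENSAMXG00000000394), which supplies carbon for fatty acids, rose by 5.38 ± 0.53, from 6.07 ± 1.74 to 311 ± 163 TPM (limma adjusted p = 0.000134). thrsp, a regulator of lipogenesis, rose by 4.62 ± 1.34. That call ended with no filter, with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without Pachon_starved replicate 1 or Pachon_refed replicate 1 (limma adjusted p from 0.0224 up to 0.0928 with 1 library left out). gck rose by 4.75 ± 1.20, ATAD3A by 4.65 ± 0.45, tomm40l, a channel for mitochondrial protein import, by 4.65 ± 0.50 and prodha, which breaks down proline, by 4.61 ± 0.59 (limma adjusted p of 0.0113 or lower). Of the genes fixed in advance, pparab, a nuclear receptor of fatty acid oxidation, rose by 2.73 ± 0.46, gpam by 1.32 ± 0.26, hmgcrb, the rate-limiting step of cholesterol synthesis, by 1.31 ± 0.25 and the clock gene per2 by 0.92 ± 0.18 (limma adjusted p of 0.00315 or lower). Among genes that fell, acsl4b, which activates long-chain fatty acids, fell by 4.35 ± 0.42, from 86.3 ± 35.1 to 3.48 ± 2.33 TPM (limma adjusted p = 0.00012). Likewise foxo1a, a transcription factor of fasting metabolism, fell by 4.33 ± 0.95, from 26.8 ± 8.96 to 0.333 ± 0.146 TPM (limma adjusted p = 0.00541). The Wnt antagonist gene nkd3 fell by 4.29 ± 0.69, slc22a16 fell by 4.11 ± 0.45, and glula fell by 3.91 ± 0.81. Also lower, ddit4 fell by 3.86 ± 0.71, spns3 (1 of many), a lysosomal membrane transporter family gene, fell by 3.57 ± 0.40 and the autophagy kinase gene ulk1a fell by 3.54 ± 0.50 (limma adjusted p of 0.00383 or lower).

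Of all 13157 tested genes, 3019 were called higher and 1005 lower on Pachón refeeding, against 1188 and 1273 on surface refeeding. Counts of members called higher are therefore not directly comparable between the populations, and the excess of higher calls depended on the scaling, as given below. Ribosome biogenesis had the most members called in Pachón cavefish: 36 of 43 members rose, 0 fell and 7 passed no test (36 and 0 adjusted over the list alone). The ribosome biogenesis list had a median of 2.22 (camera adjusted p = 1.2e-14, adjusted p = 0.709 with an estimated correlation). Erythrocyte markers had summed TPM of 651 to 674 in starved and 293 to 423 in refed Pachón libraries. Their list was not called: 1 of 12 members rose, 0 fell and 11 passed no test (1 and 0 adjusted over the list alone, camera adjusted p = 0.128, adjusted p = 0.882 with an estimated correlation, fry adjusted p = 0.611). Summed TPM of intestine markers were 43.6 to 63.9 in starved and 39.2 to 40 in refed Pachón libraries, of neutrophil markers 50.5 to 54.9 and 56.5 to 79.6, of skeletal muscle markers 4.05 to 11.1 and 11.3 to 14.7, and of endocrine pancreas markers 0.570 to 1.09 and 1.12 to 3.10. The ribosome biogenesis members rrp12, wdr75, nat10 and utp20 rose by 3.43 ± 0.33, 2.99 ± 0.28, 2.74 ± 0.26 and 1.90 ± 0.18. Of the proteasome list 22 of 36 members rose, 0 fell and 14 passed no test (27 and 0 adjusted over the list alone). The list was called (camera adjusted p = 3.23e-06, adjusted p = 0.882 with an estimated correlation), with psmd12 at 2.48 ± 0.39 and psmd7 at 1.64 ± 0.27. In fatty acid synthesis 12 of 27 members rose, 1 fell and 14 passed no test (17 and 1 adjusted over the list alone). The fatty acid synthesis list was called (camera adjusted p = 0.00809, adjusted p = 0.882 with an estimated correlation), with pgd, which makes NADPH, at 3.25 ± 0.58. Triglyceride synthesis and lipid droplet genes gave no list call, with 7 of 23 higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.74, adjusted p = 0.917 with an estimated correlation). Among these were fitm2, which helps to form lipid droplets, at 2.48 ± 0.40 and dgat1b, the last step of triglyceride synthesis, at 1.73 ± 0.19. In glycolysis 12 of 29 members rose, 1 fell and 16 passed no test (15 and 2 adjusted over the list alone). The glycolysis list was called (camera adjusted p = 0.00736, adjusted p = 0.312 with an estimated correlation), with pfkfb2b at 2.65 ± 0.32, pgam1a at 2.49 ± 0.25 and pgk1 at 2.32 ± 0.29. In amino acid breakdown 23 of 55 members rose, 1 fell and 31 passed no test (26 and 1 adjusted over the list alone), and the list was called (camera adjusted p = 0.0143, adjusted p = 0.709 with an estimated correlation). Its member gldc, which cleaves glycine, rose by 3.43 ± 0.54, aass, which degrades lysine, by 2.53 ± 0.31 and dbt, which acts on branched-chain amino acids, by 1.48 ± 0.20. Respiratory chain genes rose in 17 of 51 members and fell in 0 (17 and 0 adjusted over the list alone), with cyc1 at 1.88 ± 0.43 and uqcrc2b at 0.94 ± 0.18 (camera adjusted p = 0.0143, adjusted p = 0.882 with an estimated correlation). This call ended without Pachon_refed replicate 1 (adjusted p = 0.0627), at 5 TPM or more in 3 libraries (adjusted p = 0.0727), under median-of-ratios scaling (7 rose, adjusted p = 0.12) and under quantile normalization (adjusted p = 0.103). Among unfolded protein response genes 12 of 32 members rose, 1 fell and 19 passed no test (14 and 1 adjusted over the list alone), with hyou1 at 4.23 ± 0.92 and eif2ak3 at 1.36 ± 0.32. The list call (camera adjusted p = 0.0143, adjusted p = 0.882 with an estimated correlation) ended without Pachon_starved replicate 3 (adjusted p = 0.0597) and at 5 TPM or more in 3 libraries (adjusted p = 0.069).

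Groups called down against other genes in refed Pachón cavefish included autophagy and lysosome, where 1 of 41 members rose, 16 fell and 24 passed no test (1 and 16 adjusted over the list alone). The autophagy and lysosome list had a median of -0.27 (camera adjusted p = 1.5e-06, adjusted p = 0.234 with an estimated correlation). In fatty acid oxidation 3 of 39 members rose, 7 fell and 29 passed no test (2 and 4 adjusted over the list alone). The list was called down (camera adjusted p = 0.00151, adjusted p = 0.882 with an estimated correlation). Its member pdk2a, another brake on glucose oxidation, fell by 2.97 ± 0.56, crot fell by 2.67 ± 0.27 and acadvl fell by 1.49 ± 0.24. Insulin and growth hormone signalling genes rose in 3 of 41 members and fell in 8 (3 and 8 adjusted over the list alone). In that list socs2, which damps growth hormone signalling, fell by 3.32 ± 0.53 and ptpn1, which damps insulin signalling, rose by 1.29 ± 0.21. The list call (camera adjusted p = 0.0173, adjusted p = 0.825 with an estimated correlation) ended under median-of-ratios scaling (adjusted p = 0.0613) and quantile normalization (adjusted p = 0.0554). Cytosolic ribosomal protein genes had no member called and a median of -0.26 (camera adjusted p = 1.96e-06, adjusted p = 0.882 with an estimated correlation), a call that ended under quantile normalization. Under median-of-ratios scaling 31 of the 75 genes fell. Acute phase, complement and coagulation genes had 1 member higher (0 and 0 adjusted over the list alone) and a median of -0.15 (camera adjusted p = 0.0173, adjusted p = 0.882 with an estimated correlation). This call ended with no filter, under quantile normalization, with library weights, with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without Pachon_starved replicate 1 or Pachon_refed replicate 1 (adjusted p up to 0.111 with 1 library left out). By fry, glycolysis (adjusted p = 2.82e-05), ribosome biogenesis (adjusted p = 0.000352), and amino acid breakdown (adjusted p = 0.000352) were called. So were autophagy (adjusted p = 0.000631), fatty acid synthesis (adjusted p = 0.00563), the proteasome (adjusted p = 0.0339) and the respiratory chain (adjusted p = 0.0368), while camera with an estimated correlation called none (lowest adjusted p = 0.234). The other 5 lists that camera called were not called by fry (lowest adjusted p = 0.239). In all, 3019 genes were higher and 1005 lower (4024 called by limma of 13157), of which 1974 and 586 changed at least 2-fold. The balance of higher and lower calls depended on the scaling of libraries, since the median log2 fold change of all tested genes was 0.17 for TPM as deposited and -0.09 under median-of-ratios scaling. Higher calls made up 75.0% for TPM as deposited, 49.3% under median-of-ratios scaling (2028 higher, 2083 lower) and 53.3% under quantile normalization (2163 higher, 1895 lower).

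**Figure D3:**
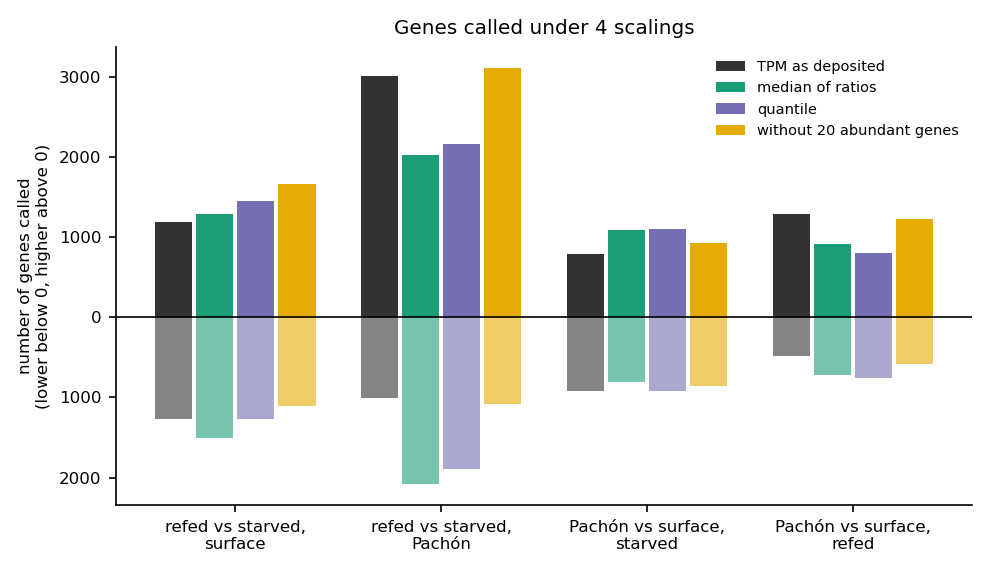
Number of genes called higher (above 0) and lower (below 0) in 4 comparisons for TPM as deposited, median-of-ratios scaling, quantile normalization and TPM rescaled without the 20 most abundant genes. In Pachón cavefish refeeding gave 3019 higher and 1005 lower genes for TPM as deposited and 2028 higher and 2083 lower under median-of-ratios scaling.

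The third comparison asked how the liver of starved Pachón cavefish differed from that of starved surface fish. The tyrosine-degrading gene hpdb (ENSAMXG00000015502) was higher in Pachón cavefish by 7.18 ± 0.54, with 0.620 ± 0.972 TPM in surface fish and 255 ± 184 TPM in Pachón cavefish (SD, n = 3, limma adjusted p = 7.61e-06). The exchange factor gene arhgef19 was higher by 4.93 ± 0.28, the membrane protein gene cdcp1a by 4.84 ± 0.19, and the aminopeptidase gene anpepb by 4.45 ± 0.45. Further genes higher there were nisch by 4.44 ± 0.31, agmat, which hydrolyses agmatine, by 4.37 ± 0.59 and the kinesin gene kif1ab, at 0.250 ± 0.0529 TPM in surface fish, by 4.29 ± 0.35 (limma adjusted p of 0.000752 or lower). apoa4a (1 of many), an apolipoprotein gene, was lower by 5.65 ± 0.96, from 169 ± 248 TPM in surface fish to 0.320 ± 0.0954 TPM in Pachón cavefish (limma adjusted p = 0.00344). In Pachón cavefish rassf1 was lower by 4.71 ± 0.55, ppdpfa was lower by 4.20 ± 0.79, and mblac1 was lower by 4.09 ± 0.80. Likewise miox, which oxidises inositol, was lower by 3.79 ± 0.42 and akr1b1 (1 of many), an aldose reductase gene, was lower by 3.71 ± 0.35 (limma adjusted p of 0.00737 or lower). Symbols marked 1 of many are shared by several genes. How reads were divided between them is not known here, so their values are uncertain. Mean levels were under 1 TPM in surface fish for hpdb, cdcp1a and kif1ab, and in Pachón cavefish for rassf1. Reads that fail to align could also give such values, which was left open for these genes, as described under other observations. Triglyceride synthesis genes were higher in 4 of 23 members and lower in 1 (5 and 1 adjusted over the list alone) without a list call (camera adjusted p = 0.175, adjusted p = 0.903 with an estimated correlation). Within the list gpam was higher by 1.99 ± 0.26 and dgat1b by 1.33 ± 0.19 (limma adjusted p of 0.00114 or lower).

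Of the fatty acid oxidation list 0 of 39 members were higher, 7 lower and 32 passed no test in starved Pachón cavefish (0 and 10 adjusted over the list alone). The fatty acid oxidation list had a median of -0.47 (camera adjusted p = 0.0197, adjusted p = 0.903 with an estimated correlation). Of its members mgll was lower by 2.28 ± 0.19, the peroxisomal genes acaa1 and hsd17b4 were lower by 2.16 ± 0.36 and 1.65 ± 0.22, and the ketone body gene bdh1 was lower by 0.97 ± 0.20 (limma adjusted p of 0.00864 or lower). The list was not called by fry (adjusted p = 0.117), and its camera call ended with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without Surface_starved replicate 2, Pachon_starved replicate 2 or Pachon_starved replicate 3 (adjusted p up to 0.19 with 1 library left out). In amino acid breakdown 5 of 55 members were higher, 4 lower and 46 passed no test (7 and 5 adjusted over the list alone). The amino acid breakdown list had a median of 0.49 (camera adjusted p = 0.00157, adjusted p = 0.651 with an estimated correlation), and fry gave adjusted p = 0.0391. The only other list that fry called was that of adipocyte markers, with 2 of 6 tested members lower (0 and 2 adjusted over the list alone, fry adjusted p = 0.0391, camera adjusted p = 0.195, adjusted p = 0.903 with an estimated correlation). Markers of stellate cells and fibroblasts had summed TPM of 311 to 356 in starved Pachón cavefish and 432 to 719 in starved surface fish. Of their list 0 of 13 members were higher, 3 lower and 10 passed no test (0 and 5 adjusted over the list alone), without a list call (camera adjusted p = 0.175, adjusted p = 0.903 with an estimated correlation, fry adjusted p = 0.0704). Summed TPM of neutrophil markers were 50.5 to 54.9 in starved Pachón cavefish and 93.1 to 240.2 in starved surface fish. Those of skeletal muscle markers were 4.05 to 11.1 and 1.24 to 1.57, and those of vitellogenin and egg-protein genes 3069 to 4083 and 4237 to 7188. Histidine-degrading hal was higher by 1.41 ± 0.22, while sdsl, a serine dehydratase gene, was lower by 1.57 ± 0.24 and afmid, of the tryptophan pathway, was lower by 1.40 ± 0.25. Cytosolic ribosomal protein genes had 2 members higher (0 and 0 adjusted over the list alone) and a median of 0.22 (camera adjusted p = 0.00157, adjusted p = 0.903 with an estimated correlation). Ribosome biogenesis had 2 members lower (0 and 0 adjusted over the list alone) and a median of -0.56 (camera adjusted p = 0.00722, adjusted p = 0.903 with an estimated correlation). The first call also ended under quantile normalization, and both ended without Pachon_starved replicate 1 (adjusted p up to 0.139 and 0.139 with 1 library left out). Among 13157 genes 795 were higher and 924 lower in Pachón cavefish by limma (1719 called), 600 and 560 at least 2-fold. The number called was 881 without Pachon_starved replicate 3 and 1064 without Pachon_starved replicate 1, and median-of-ratios scaling moved the share of higher calls from 46.2% to 57.5% (1087 higher, 804 lower).

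The fourth comparison asked how the populations differed after the meal. Among genes of fat synthesis, fasn had 38.7 ± 45.8 TPM in refed surface fish and 1267 ± 1095 TPM in refed Pachón cavefish, a log2 fold change of 5.30 ± 0.80 (SD, n = 3, limma adjusted p = 0.00146). Citrate lyase gene aclya was higher by 3.74 ± 0.53 and acss2, which makes acetyl-CoA from acetate, by 1.29 ± 0.21. The triglyceride synthesis genes dgat1b, dgat2 and gpam were higher by 2.78 ± 0.19, 1.86 ± 0.39 and 1.87 ± 0.26 (limma adjusted p of 0.0103 or lower). scd had 553 ± 301 and 3412 ± 3621 TPM, a log2 fold change of 2.25 ± 1.06 that was not called (limma adjusted p = 0.183). lpin1, which makes diacylglycerol, and pparab were higher by 1.68 ± 0.46 and 1.71 ± 0.46. Both calls ended without Surface_refed replicate 2 or 3 or Pachon_refed replicate 3, with only the 6 refed libraries, with no filter, with replicate numbers as a block, and under median-of-ratios scaling and quantile normalization. That of lpin1 also ended without Pachon_refed replicate 2 and that of pparab without Pachon_refed replicate 1, alone or with Surface_starved replicate 2 (limma adjusted p up to 0.126 and 0.11 with 1 library left out). Beyond fat synthesis, hpdb was higher by 8.70 ± 0.54, from 0.717 ± 0.591 TPM in surface fish to 691 ± 119.6 TPM in Pachón cavefish (limma adjusted p = 2.08e-06). kif1ab was higher by 4.88 ± 0.35, nisch by 4.78 ± 0.31 and mdka, a secreted growth factor gene, by 4.75 ± 0.50 (limma adjusted p of 0.000122 or lower). A channel gene, cngb3.2, had 29.3 ± 5.0 TPM in Pachón cavefish and was listed at 0 in all 3 refed surface libraries. Mean levels of hpdb, kif1ab and cngb3.2 were under 1 TPM in refed surface fish, and failed alignment of surface reads was left open for them. Of the genes lower in Pachón cavefish, apoa4a (1 of many) was lower by 4.67 ± 0.96 and akr1b1 (1 of many) was lower by 4.53 ± 0.35. Glutathione peroxidase gene gpx1a was lower by 4.46 ± 0.61, ssr2 (1 of many) was lower by 3.59 ± 0.68 and rgrb, an opsin gene, was lower by 3.51 ± 0.37 (limma adjusted p of 0.00894 or lower).

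Amino acid breakdown had the most members called between refed populations, where 20 of 55 members were higher, 2 lower and 33 passed no test (27 and 3 adjusted over the list alone). The amino acid breakdown list had a median of 0.87 (camera adjusted p = 0.000908, adjusted p = 0.502 with an estimated correlation). prodha was higher by 4.71 ± 0.59, mat1a, which makes S-adenosylmethionine, by 1.98 ± 0.25 and asl, of the urea cycle, by 1.53 ± 0.16. In fatty acid synthesis 6 of 27 members were higher, 0 lower and 21 passed no test (7 and 0 adjusted over the list alone). The fatty acid synthesis list had a median of 0.90 (camera adjusted p = 0.039, adjusted p = 0.916 with an estimated correlation). That list call ended with library weights, with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without Surface_refed replicate 2 or 3 or Pachon_refed replicate 1 (adjusted p up to 0.184 with 1 library left out). Triglyceride synthesis genes were higher in 5 of 23 members and lower in 1 (6 and 1 adjusted over the list alone) without a list call (camera adjusted p = 0.108, adjusted p = 0.916 with an estimated correlation), although quantile normalization gave adjusted p = 0.0478. Glycolysis genes were higher in 6 of 29 members and lower in none (12 and 0 adjusted over the list alone), among them eno3 by 1.31 ± 0.24 and pfkpa by 1.55 ± 0.34. The list was not called by camera for TPM as deposited (camera adjusted p = 0.0613, adjusted p = 0.582 with an estimated correlation). It was called under median-of-ratios scaling (camera adjusted p = 0.0487) and quantile normalization (camera adjusted p = 0.0235). Respiratory chain genes had a positive change in 48 of 51 members, of which 2 passed the test (1 and 0 adjusted over the list alone), with ndufa4 at 3.96 ± 0.65 (camera adjusted p = 0.00478, adjusted p = 0.916 with an estimated correlation). Acute phase, complement and coagulation genes had 1 member lower (0 and 0 adjusted over the list alone) and a median of -0.25 (camera adjusted p = 0.00478, adjusted p = 0.916 with an estimated correlation). Both this call and that of the respiratory chain ended without Surface_refed replicate 3 or Pachon_refed replicate 1 (adjusted p up to 0.0872 and 0.109 with 1 library left out). Bile acid genes were lower in 2 of 18 members and higher in 1 (1 and 2 adjusted over the list alone), among them hsd3b7, an enzyme of bile acid synthesis, which was lower by 1.44 ± 0.24. The list call (camera adjusted p = 0.0368, adjusted p = 0.502 with an estimated correlation) ended with no filter, under quantile normalization, with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without Surface_refed replicate 2 or Pachon_refed replicate 1 (adjusted p up to 0.131 with 1 library left out). Biliary epithelium markers had summed TPM of 824 to 1189 in refed Pachón and 1413 to 1773 in refed surface libraries. Of their list 3 of 12 members were higher, 0 lower and 9 passed no test (3 and 0 adjusted over the list alone), without a list call (camera adjusted p = 0.569, adjusted p = 0.916 with an estimated correlation, fry adjusted p = 0.741). In the same order the summed TPM of neutrophil markers were 56.5 to 79.6 and 126 to 158, and of adipocyte markers 168 to 363 and 392 to 919. Those of intestine markers were 39.2 to 40 and 13.3 to 24.9, of skeletal muscle markers 11.3 to 14.7 and 1.35 to 2.10, and of lymphocyte markers 7.87 to 10.6 and 4.10 to 7.15. In ribosome biogenesis 3 members were higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.0443, adjusted p = 0.916 with an estimated correlation). That call ended at a pseudocount of 0.1, under median-of-ratios scaling (adjusted p = 0.054), with library weights and with TPM rescaled without the 20 most abundant genes. It also ended with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out, and without any of Surface_starved replicate 3, Surface_refed replicate 2 or 3, Pachon_starved replicate 2 and Pachon_refed replicate 1 (adjusted p up to 0.4 with 1 library left out). By fry, amino acid breakdown (adjusted p = 0.000228), glycolysis (adjusted p = 0.000578), triglyceride synthesis (adjusted p = 0.00698), fatty acid synthesis (adjusted p = 0.0398) and the respiratory chain (adjusted p = 0.0427) were called, but with an estimated correlation camera called none (lowest adjusted p = 0.502). Fry also called antioxidant and xenobiotic metabolism (adjusted p = 0.00639), autophagy (adjusted p = 0.0144), gluconeogenesis (adjusted p = 0.0153), DNA repair (adjusted p = 0.0398) and intestine markers (adjusted p = 0.0491). Camera called none of these 5 (lowest adjusted p = 0.277, lowest adjusted p = 0.916 with an estimated correlation). Nor did fry call the acute phase, bile acid or ribosome biogenesis lists (lowest adjusted p = 0.0505). Among 13157 genes 1292 were higher and 476 lower in refed Pachón cavefish by limma (1768 called), 829 and 336 at least 2-fold. The number called was 1077 without Pachon_refed replicate 2 and 1109 without Surface_refed replicate 2. Higher calls made up 73.1% for TPM as deposited, 56.1% under median-of-ratios scaling (917 higher, 719 lower) and 51.5% under quantile normalization (804 higher, 756 lower).

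**Figure D4:**
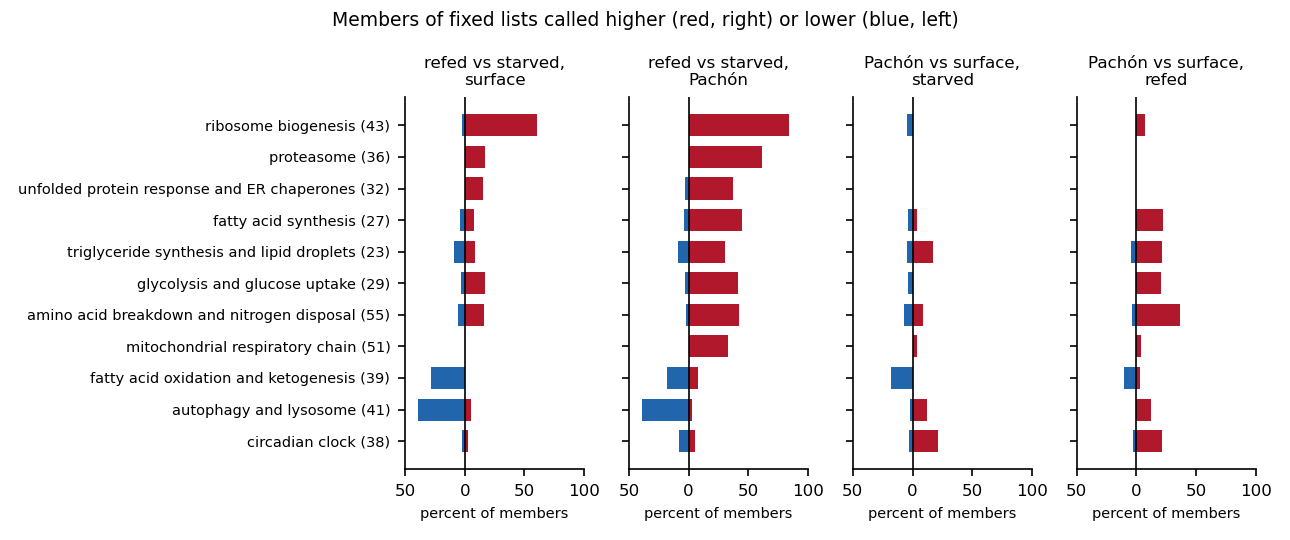
Percent of the members of 11 fixed gene lists called higher (right of 0) or lower (left of 0) in the 4 comparisons, with the number of tested members in parentheses. After refeeding 26 and 36 of 43 ribosome biogenesis members rose in surface fish and Pachón cavefish and 16 of 41 autophagy and lysosome members fell in each. Of all 13157 tested genes 1188 and 3019 rose and 1273 and 1005 fell in the same order.

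The last comparison asked whether the response to the meal differed between the populations. Of 13157 genes, 8 responded more strongly upward in Pachón cavefish and 1 less by limma (9 called, 2176 at an unadjusted p under 0.05). The apoptosis inhibitor gene triap1 (ENSAMXG00000034513) went from 12.3 ± 2.91 to 10.9 ± 1.84 TPM in surface fish and from 5.03 ± 0.957 to 26.1 ± 5.71 TPM in Pachón cavefish (SD, n = 3), a difference in response of 2.30 ± 0.33 (limma adjusted p = 0.0371). The kinase gene NEK3 (ENSAMXG00000009911) went from 2.13 ± 0.104 to 0.313 ± 0.0737 TPM and from 2.22 ± 0.490 to 5.49 ± 1.47 TPM in these populations, a difference of 2.25 ± 0.26 (limma adjusted p = 0.0346). Both calls ended without any of Surface_refed replicate 2, Pachon_starved replicates 1 and 3 and Pachon_refed replicates 1 and 2. That of triap1 also ended without Surface_starved replicate 2 or 3, Surface_refed replicate 3, Pachon_starved replicate 2 or Pachon_refed replicate 3 (limma adjusted p up to 0.159 and 0.137 with 1 library left out). Over all alternatives the call of triap1 ended in 16 of 24, among them a pseudocount of 0.1, the filter at 5 TPM, median-of-ratios scaling and TPM rescaled without the 20 most abundant genes, and that of NEK3 in 7 of 23. In both cases these alternatives include replicate numbers as a block, which left 0 genes called. The lipogenic genes fasn and scd differed in response by 3.92 ± 1.13 (limma adjusted p = 0.174) and 4.08 ± 1.5 (limma adjusted p = 0.227), which did not pass the test. Camera tested each list against the other genes, whose median difference was 0.29 over all tested genes. It called up ribosome biogenesis, with a median difference of 1.12 (camera adjusted p = 1.35e-07, adjusted p = 0.85 with an estimated correlation), fatty acid synthesis with 1.42 (camera adjusted p = 0.000973, adjusted p = 0.85 with an estimated correlation) and the respiratory chain with 0.53 (camera adjusted p = 0.00241, adjusted p = 0.85 with an estimated correlation). It called down acute phase, complement and coagulation genes, with a median difference of -0.29 (camera adjusted p = 3.59e-06, adjusted p = 0.85 with an estimated correlation), and hepatocyte markers with -0.52 (camera adjusted p = 0.00345, adjusted p = 0.85 with an estimated correlation). Cytosolic ribosomal protein genes were also called down against other genes (camera adjusted p = 0.000883, adjusted p = 0.897 with an estimated correlation), although their median change was negative in both populations (-0.19 and -0.26) and their own median difference was -0.07. None of these 6 lists was called by fry (lowest adjusted p = 0.0986). The only list fry called was glycolysis (adjusted p = 0.00775, 23 of 29 members with a positive difference, 3 and 0 adjusted over the list alone), which camera did not call (camera adjusted p = 0.119, adjusted p = 0.85 with an estimated correlation). The list calls of the respiratory chain, acute phase genes and hepatocyte markers ended with both Surface_starved replicate 2 and Pachon_refed replicate 1 left out (adjusted p = 0.0562, 0.0954 and 0.267), where the median of acute phase genes was 0.05. That of the respiratory chain also ended without Surface_refed replicate 3 (adjusted p = 0.134). That of cytosolic ribosomal proteins ended without Surface_refed replicate 2, Pachon_starved replicate 1 or Pachon_refed replicate 1 (adjusted p up to 0.169 with 1 library left out), and that of hepatocyte markers without Surface_starved replicate 2 (adjusted p = 0.198). Both of the latter also ended under quantile normalization, and that of hepatocyte markers with no filter and with library weights. No member of these 6 lists was called over all genes, and 10 of ribosome biogenesis and 4 of fatty acid synthesis were called higher when adjusted over the list alone. The number of genes called was 0 without any of Surface_refed replicate 2, Pachon_starved replicate 1 or 3 and Pachon_refed replicate 1 or 2. It was 55 without Surface_starved replicate 1, 19 without Surface_refed replicate 1, 4 without Pachon_starved replicate 2 and 2 without Pachon_refed replicate 3. Calls split 7 higher to 8 lower under median-of-ratios scaling and 8 to 10 under quantile normalization.

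The responses to the meal were alike in much of the transcriptome. Across the 13157 tested genes, which are not independent replicates, the log2 fold changes of the 2 populations correlated with Pearson r = 0.691, in comparisons that share no library. Of the called genes 1012 were higher in both, where independent lists would share 273, 546 were lower in both, against 97.2, and 7 went opposite ways. The population differences of starved and refed fish correlated with r = 0.669 across the same genes. There 495 genes were higher in Pachón cavefish in both states, against 78.1 for independent lists, 268 were lower in both, against 33.4, and 6 went opposite ways. In each pair of comparisons the calls used the same spread of a gene, from the fit of all libraries. A gene with a small spread is thus more easily called in both, so the counts for independent lists are a low reference.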

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

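No test in this part was chosen after its result was seen. The refeeding response was marked for a closer look because a test of the difference between surface fish and Pachón cavefish called 9 genes and 6 gene lists. The named genes were triap1, with a log2 difference in response of 2.30, and NEK3, with 2.25. The lists were fatty acid synthesis (median difference 1.42), ribosome biogenesis (1.12), the respiratory chain (0.53), cytosolic ribosomal proteins (-0.0726), acute phase genes (-0.287) and hepatocyte markers (-0.519), beside a median of 0.29 over all genes. With an estimated correlation none of the 6 lists was called (lowest adjusted p = 0.85).

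The libraries were split in 100 ways within the design, the real one included, to see how often as many genes would be called. As many as the 9 genes were called in 11 of 100 splits, with up to 2635 in another split, and as many as the 6 lists in 97 of 100, with up to 19. By this test the number of genes called did not stand out from that of other splits (11 of 100). The splits mix starved and refed libraries, so the refeeding effect enters their contrast and their spread. They are no clean reference for chance, and a chance origin of the difference in response was neither shown nor excluded. Splits that exchange the feeding labels within 1 population measure the refeeding effect itself, so the highest counts are not chance alone. A biological difference between the populations is not excluded by these values.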

How the results depend on the processing

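In this part, 2 settings were chosen after seeing the data: TPM rescaled without the 20 most abundant genes, and the fit without Surface_starved replicate 2 and Pachon_refed replicate 1. Of 138 calls of single genes named in the report, 128 stood and 0 turned in sign under the 23 to 25 alternatives run for single genes, which left out the stricter thresholds. These genes were mostly named because their calls stood, and of all 370 called genes from the naming rule 214 stood. Of 34 list calls, 0 stood under all. Where a count moved, the cause was not tested, apart from stricter thresholds and fewer libraries or genes.

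At 5 TPM or more in 3 libraries, 969 genes were called between starved and 1017 between refed populations. At 2-fold or more, surface refeeding gave 1450 genes, Pachón refeeding 2560 and refed populations 1165. At an adjusted p under 0.01 the counts were 855 and 2337 for refeeding in surface fish and Pachón cavefish, 660 and 735 for starved and refed populations, and 0 for the difference in response. With only its 6 libraries, surface refeeding gave 837. The difference in response gave 1 gene at a pseudocount of 0.1, 19 at 5, 21 with no filter, 0 at 5 TPM, and 15 under median-of-ratios scaling. It gave 18 under quantile normalization, 35 with library weights, 1 with TPM rescaled and 0 without Surface_starved replicate 2 and Pachon_refed replicate 1. With an estimated correlation 0 lists were called in all 5 comparisons, and fry called 4 for surface refeeding, 7 for Pachón refeeding, 2 for starved and 10 for refed populations, and 1 for the difference in response.

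The difference in the PPARG response turned to -0.25 under median-of-ratios scaling, -0.21 under quantile normalization, -0.0073 with library weights and -0.0531 with TPM rescaled, and was 0.46 without Surface_starved replicate 2 and Pachon_refed replicate 1. With 1 library left out it went from -0.23 (Pachon_starved replicate 1) to 0.42 (Pachon_starved replicate 3), and was also negative without Surface_starved replicate 1 (-0.16), Surface_refed replicate 1 (-0.0084) or Pachon_refed replicate 3 (-0.02). The other PPARG changes kept their sign: 0.15 to 0.63 for surface refeeding, 0.14 to 0.79 for Pachón refeeding, 1.40 to 2.06 between starved and 1.72 to 2.00 between refed populations.

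With 1 library left out, surface refeeding gave 1406 to 2387 genes and 5 to 8 lists, and Pachón refeeding 2769 to 4325 and 11 to 13. Likewise starved populations gave 881 to 1794 and 2 to 5, refed populations 1077 to 1983 and 2 to 8, and the difference in response 0 to 55 and 6 to 8. The lowest counts of genes, not of lists, were without Surface_refed replicate 3, Pachon_refed replicate 1, Pachon_starved replicate 3 and Pachon_refed replicate 2 in the first 4. The correlation of refeeding responses was 0.598 to 0.719 and that of population differences 0.589 to 0.69. Replicate numbers as a block gave 1911, 3535, 1298, 1352 and 0 genes. The deviations of libraries from their group means were also correlated across genes, between libraries of different groups. For equal replicate numbers these correlations were -0.245 to 0.123 (median -0.0579), against a median of 0.0316 for other numbers. By these deviations 0 of 12 libraries correlated best with its own number.

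For some lists that were not called the direction of the test turned, and the median of the list in each such setting is given here. For Ppar gamma targets it was -0.0535 between starved populations with no filter, -0.074 at 5 TPM, -0.234 with library weights, 0.0008 without Surface_starved replicate 2 and Pachon_refed replicate 1, and -0.0331 by fry. With 1 library left out it went from -0.298 to 0.0674, and the direction turned without Surface_starved replicate 2 (0.0008). Between refed populations it had -0.218 under quantile normalization, -0.046 by fry, and -0.171 to 0.183 with 1 library left out. There the direction turned without Surface_refed replicate 1 (0.174). Triglyceride synthesis on Pachón refeeding had 0.136 without both libraries and 0.136 to 0.664 with 1 left out. Fatty acid synthesis on surface refeeding went from -0.128 to 0.581, and between refed populations the circadian list from 0.151 to 0.334 and the antioxidant list from 0.119 to 0.312. Fatty acid synthesis turned without Surface_starved replicate 1 (-0.128) or Surface_refed replicate 1 (-0.11). The circadian list turned without Pachon_refed replicate 3 (0.216) and the antioxidant list without Surface_refed replicate 3 (0.119). Biliary epithelium markers between refed populations had -0.33 by fry.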

Other observations

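Some clock genes differed between the populations, while most members of the circadian list passed no test. The time of day of dissection is not among the sample labels used here. A difference in sampling time therefore cannot be told from a population difference, nor from the rise of per2 after refeeding in Pachón cavefish. The clock repressor gene cry1ab was higher in Pachón cavefish by 1.79 ± 0.31 when starved and 1.52 ± 0.31 when refed (limma adjusted p of 0.00844 or lower). The clock output gene dbpb was higher by 2.33 ± 0.42 and 2.79 ± 0.42. The repressor gene ciarta was higher by 1.81 ± 0.34 and the nuclear receptor gene rorcb was lower by 1.37 ± 0.25 in starved Pachón cavefish, and bhlhe41 was higher by 1.06 ± 0.21 in refed ones. Of the circadian list 8 of 38 members were higher, 1 lower and 29 passed no test in starved fish (10 and 7 adjusted over the list alone), without a list call (camera adjusted p = 0.229, adjusted p = 0.903 with an estimated correlation). There its median (-0.14) and mean (0.13) differed in sign. In refed fish 8 of 38 members were higher, 1 lower and 29 passed no test (9 and 3 adjusted over the list alone), again without a list call (camera adjusted p = 0.81, adjusted p = 0.952 with an estimated correlation).

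Of the genes with the symbol mt2 (1 of many), which encode metallothioneins that bind zinc and copper, ENSAMXG00000043108 was higher in Pachón cavefish by 3.38 ± 0.28 in starved fish, from 228 ± 76.7 to 2317 ± 393 TPM, and by 3.55 ± 0.28 in refed fish (limma adjusted p of 1.87e-05 and 1.25e-05). ENSAMXG00000035436 was higher by 5.66 ± 0.38 in refed fish and was listed at 0 in all 3 starved surface libraries. How reads were divided between copies with the same symbol is not known here, so the level of each is uncertain. The summed TPM of 13 neutrophil markers averaged 173 and 146 in starved and refed surface fish and 53.2 and 69.8 in starved and refed Pachón cavefish.

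The tests of the share of higher calls and of Surface_starved replicate 2 below, and the second count of genes near 0, were chosen after the result was seen. After refeeding, 75.0% of the called genes were higher in Pachón cavefish. A few abundant genes taking the transcripts did not account for it, since 74.2% were higher with the 20 most abundant genes left out, and neither did noise of low genes, since 78.1% were higher at 5 TPM or more in 3 libraries. Under median-of-ratios scaling 49.3% were higher, but that scaling centres the ratios, so scaling and a broad biological rise could not be told apart.

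Of 11 genes near 0 in one population and at 10 TPM or more in the other in both states, 9.09% (95% interval 0.23% to 41.3%) were near 0 in Pachón cavefish. By group means this held for 29.7% of 37 genes (15.9% to 47.0%). Reads of surface fish that fail to align could give such an excess. The values (9.09% and 29.7%) leave this open, as the genome build is not given in the sources used here. Among the 37 genes are hpdb, cdcp1a, kif1ab, cngb3.2, rassf1 and mt2 (1 of many, ENSAMXG00000035436), whose population differences are described above. Only 1 of the 11 genes, kif1ab, had a copy with the same symbol, and in 0% did the summed copies come within 2-fold, and of the 37 genes by group means 5 had copies, of which 1 came within 2-fold, too few to judge reads assigned to a copy. A difference in expression between the populations was not separated from these.

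Surface_starved replicate 2 stood apart from the other starved surface libraries. Its hepatocyte markers summed to 85221 TPM, against 190970 and 187888 TPM in those. Its fabp10a level was 27975 TPM, against 84550 and 78773 TPM, and fabp10a was not its most abundant gene. It had 4203 TPM of vtg3, an egg yolk precursor that oestrogen induces in the liver. In this library vitellogenin and egg-protein genes summed to 7188 TPM, against 4237 and 4449 TPM in those. Its ovary markers summed to 8.71 TPM, above 4.81 and 5.91 TPM in the other starved surface libraries and below 12.06 TPM in a refed Pachón library, so ovary tissue in the sample was neither shown nor excluded. The values argued against a refed fish labelled as starved, since the library lay at 0.283 between the starved (0) and refed (1) surface libraries. The lowest refed surface library lay at 0.81. The other starved surface libraries lay at -0.0769 and 0.0769, so it did not match them either. The sex of the fish is not among the labels, so no biological explanation was tested.

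With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called the most genes (1 of 10) for surface refeeding (2461 against up to 121 in another split), Pachón refeeding (4024 against 3), starved populations (1719 against 0) and refed populations (1768 against 0). As many lists as the real 6, 12, 4 and 6 were called in 10, 3, 10 and 9 of the 10 splits, with up to 17, 15, 14 and 11 lists in another split. The number of list calls by camera with the preset correlation therefore did not set the real grouping apart. Splits that mix the groups can carry part of their difference, so these counts are not chance alone. Mixing also puts part of the difference between the groups into the spread, which lowers the gene counts of the other splits. These low gene counts are therefore no clean reference for chance, and the splits do not measure how often chance would call as many genes.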
